A study of Homo sapiens with 7 samples.

How the data were processed

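The series holds 7 arrays of total RNA from HCT116 cells, amplified, labelled with biotin and hybridised to the ExonHit Human Splice Array. The deposited values are log2 values, 1 per probe set and array, normalized between arrays by the authors. RMA, Partek 6.08 and R 2.11.1 are named in the submitters' processing notes, with no role or order. Background correction, summarisation settings and genome build are not given in the sources used here. That the scale is log2 was read from the values, which run from about 1 to 13.6. Of the rows that stay under 10, 92.6% hold values in steps of the sixth decimal divided by 3 and 3.15% in steps of it divided by 2, within 0.05 of a step, as a mean of 3 or 2 numbers would.

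Probe sets were named through the platform annotation paired with the value table. Of 2108940 probe sets 1901289 had 1 gene symbol, 0 had several, and 207651 (9.85%) were not listed and are unnamed here. The number that opens a probe set's name was matched as a gene identifier to the RefSeq gene table of assembly GRCh38.p14, where 17412 of 17646 identifiers were found and 17280 carried the same gene. Symbols of 5353 genes were updated that way. Left out were 132 identifiers whose symbol disagreed with the gene table and 23 whose symbol was that of another identifier. Gene lengths come from the same table, covered 99.02% of tested genes, and are used only for ranking, because the build of the array is not named.

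Kept rows were those whose mean over all 7 arrays lay above the median of all rows, 2.95. The value of a gene is the median of its kept rows, for genes with at least 3. The relative value of a probe set is its log2 value minus the median of the kept rows of its gene, for genes with at least 5. Arrays were grouped by treatment and time from the labels: DMSO (replicate 1 at 4 h, replicate 2 at 20 h), CPT early (1, 2 and 4 h) and CPT late (15 and 20 h). The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. Nothing in the labels says whether the arrays come from separate cultures, and no time point is repeated, so p-values measure a difference against the spread between arrays taken at different times, 4 and 20 h in DMSO. The precision is limited by the 7 arrays.

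The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), fitted to all 7 arrays with 1 mean per group and 4 residual degrees of freedom, with Benjamini-Hochberg adjustment over all genes or probe sets and a threshold of 0.05. Gene lists (14 pathway lists and 4 lists of cell type markers) were tested with camera at a preset correlation of 0.01, adjusted over the 18 lists, and again with an estimated correlation. Splicing genes were compared with other genes by Fisher's exact test and logistic regression. Time-matched differences and the rank correlation with gene length carry no test. The comparisons with DMSO share their control arrays, so no overlap between them is reported. Tables and figures were made with the R package data.table, release 1.17.8, and with Python 3.11.15 and matplotlib 3.10.9.

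Genes named for each comparison were the 10 with the largest increase and the 10 with the largest decrease among those past the threshold whose groups did not overlap, or those that passed where there were fewer. Up to 4 members per pathway list with the largest absolute difference past the threshold were added, or the 1 farthest from 0 where none passed. TOP1, TDP1, CASP2, RBM8A, CDKN1A, MDM2, MYC and FOS were named whatever their value. For relative change the rule took the 5 genes with the largest share of passing probe sets, at least 3 passing, and the 10 probe sets with the largest absolute change. The splicing genes named by their share of passing probe sets were chosen after their values were seen.

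The steps were tested on simulated data made from the means and spreads of the real genes, with 100 genes changed by each size. For CPT late against DMSO over 16148 genes, 67% of the genes changed by 1 on the log2 scale and 100% of those changed by 2 were recovered. For CPT early against DMSO these were 79% and 100%. For relative change over 200000 probe sets, 0% of those changed by 1 and 17% of those changed by 2 were recovered for CPT late against DMSO, so relative changes of that size mostly escape when few probe sets change.

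Alternatives tried were the mean in place of the median, no filter and a stricter filter on dim rows at the 0.75 quantile, quantile re-normalization, eBayes without the trend or robust, each array left out in turn, time as a block, all CPT arrays as 1 group and a linear trend in log2 hours. Chosen after seeing the data were centring each array on its gene median, gene values from B, F and T probe sets only, genes in the upper tercile of level only, the estimated correlation as a count of lists, CPT late against CPT early for the splicing genes, and the letters with no filter or with rows kept by the CPT early arrays alone. Where an array left out leaves a group with 1 array, that array is assumed to vary like the others.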

Results

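HCT116 is an established human colon carcinoma cell line. Its RNA was profiled on the ExonHit Human Splice Array, which reads each gene through many separate probe sets, after treatment with 10 µM camptothecin (CPT), a drug that traps topoisomerase I on DNA. Exposures of 1, 2 and 4 h form the CPT early group (n = 3) and exposures of 15 and 20 h the CPT late group (n = 2), with 1 array for each time. Cells that received the solvent, 0.1% DMSO, for 4 or 20 h form the DMSO group (n = 2). No time point had a replicate, so each p-value measures a difference against the spread between arrays of a group taken at different times, up to 16 h apart in DMSO, which may be technical or due to time, and the number of arrays limits its precision. Each array holds log2 values for 2108940 probe sets, with array medians between 2.87 and 2.96. Across all probe sets the DMSO and CPT early arrays correlated with one another at r = 0.942 to 0.956, the late arrays correlated with these at 0.845 to 0.908, and the 15 h array correlated with the 20 h array at 0.941.

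The first comparison asked what CPT changes within 4 h. Replication-dependent histone genes, which supply histones for DNA replication, fell in CPT early: 5 of the 10 measured members were lower, 7 when adjusted over the list alone, and the list median was −1.96 on the log2 scale. H2BC18, a histone H2B gene outside the list, fell from 10.80 ± 0.10 (SD, n = 2) to 7.17 ± 0.57 (SD, n = 3), a 12.4-fold decrease. H1-2, a linker histone gene, fell from 7.82 ± 0.20 to 4.60 ± 0.07, 9.28-fold, and H2AC6 from 9.98 ± 0.15 to 6.70 ± 0.39, 9.75-fold. With no filter on dim probe sets 1 gene was lower in all, so at most 1 of these genes passed there. The fall was present on the 1 h array already, where the list median stood at −1.65 relative to the DMSO mean, and it read −2.07 at 2 h and −2.13 at 4 h. Against all other genes the histone list was lower with camera (adjusted p = 6.67e-23), and it passed with an estimated correlation too (adjusted p = 0.00806).

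Few other genes passed in CPT early. The test averages 1, 2 and 4 h, so a change that grows with time counts as spread and can be missed. By more than 2-fold, 224 genes were higher and 281 lower on the 4 h CPT array than on the 4 h DMSO array. Between the DMSO arrays these were 176 and 97, with 1 array on each side and no test. With limma and Benjamini-Hochberg adjustment, 4 of 16148 genes were higher and 11 lower, and 1147 genes had an unadjusted p under 0.05. The calls depend on the processing: with no filter on dim probe sets 0 genes were higher and 1 lower. In a fit with time as a block over the 4 and 20 h arrays 2 genes passed, and 2 in a fit of all 5 CPT arrays against DMSO. The first joins the 4 and 20 h differences and the second mixes the windows, so neither tests CPT early alone. Besides the histone genes already named, H2BC15 fell by 3.56, H2BC4 by 2.93, H2BC21 by 2.51, H2BC11 by 2.49, H4C8 by 2.42 and H2AC25 by 1.89 on the log2 scale, so that 9 of the 10 largest decreases were histone genes. The other was EPC1, a chromatin gene, which fell by 2.13. The 4 higher genes were EID2B (log2 difference 2.12 ± 0.29 SE), GTSF1L (1.66 ± 0.22), GPHA2 (1.36 ± 0.19) and the non-coding gene SLIRP-OT1 (1.10 ± 0.16). EID2B and GTSF1L rest on 3 kept probe sets each, and without the filter on dim probe sets EID2B reads −0.39. None of the 4 passed with quantile re-normalization or after centring each array on its gene median, an alternative chosen after seeing the data. Genes whose CPT early arrays did not overlap the DMSO arrays made up 21.8% of the total, against 20% by chance. The count of 15 genes rose to 32 without the 1 h array and dropped to 7 without the 2 h array, 8 without the 4 h array and 6 without either DMSO array. Of the 10 listed histone genes, 3 passed without the 2 h array or without either DMSO array. H2BC4, H4C8, H2AC25 and H2BC15 were among the calls lost without either DMSO array, with adjusted p from 0.0873 to 0.377, and so were EPC1 and each of the 4 higher genes, from 0.184 to 0.392. Without the 2 h array H2BC4 (adjusted p = 0.0554), H4C8 (0.0706), EPC1 (0.107) and the 4 higher genes (0.0869 to 0.194) were lost. Without the 4 h CPT array H4C8, EPC1 and the 4 higher genes were lost (0.0702 to 0.159), and without either late array GPHA2 and SLIRP-OT1 (0.0737 to 0.106).

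No member of the other 13 pathway lists or of the 4 lists of cell type markers passed in CPT early, and 1 did when adjusted over the list alone, a lower gene among SR proteins and SR kinases. Core spliceosome and exon junction complex genes were shifted upward as a list (median 0.18, camera adjusted p = 0.00155) and so were DNA replication genes (median 0.17, adjusted p = 0.00251), while heat shock and chaperone genes were shifted downward (median −0.12, adjusted p = 0.0425). With an estimated correlation these lists had an adjusted p = 0.908 each. Without the 20 h DMSO array the first and second of these shifts did not pass (camera adjusted p = 0.976 for both), and the heat shock shift did not pass without the 1 h CPT array (0.264), the 15 h array (0.0515), the 20 h CPT array (0.0512) or the 4 h DMSO array (0.985). Other lists passed when an array was left out. Without the 20 h DMSO array, mitosis genes and SR proteins were lower (0.00237 each), as were DNA repair genes (0.0128) and hnRNP genes (0.0166). Without the 4 h DMSO array, mitosis (median 0.15), hnRNP (0.10) and ribosomal protein genes (0.08) were higher (0.0474 each). Without the 1 h array, immediate early and ribosomal protein genes were higher (0.00744 each). The member farthest from 0 in each remaining list stayed short of the threshold. These were TRIAP1 (0.62) for p53 target genes, CCN2 (1.30) for immediate early genes, CLK1 (−1.12) for SR proteins and SR kinases and RBM5 (−0.86) for hnRNP and other splicing regulators. In the lists of the spliceosome, mitosis and DNA replication they were LSM5 (1.09), BIRC5 (0.48) and GINS2 (0.71). In those of DNA repair, apoptosis and NF-kappaB they were ERCC6 (−0.53), FADD (−0.82) and REL (−0.49), and in those of ribosomal proteins, chaperones and unfolded protein stress RPS29 (−0.45), DNAJB9 (−0.72) and CHAC1 (0.55). TOP1, the gene of the drug's target, read −0.02, and CDKN1A, the cell cycle inhibitor p21, read 0.00. TDP1 (−0.19), CASP2 (0.16), RBM8A (0.20), MDM2 (0.39), MYC (−1.19) and FOS (0.20) did not pass either.

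After 15 to 20 h of CPT the picture was much wider. Mitosis genes fell: 24 of 29 measured members were lower and 0 higher, with 25 lower when adjusted over the list alone and a list median of −1.91. CCNB1, the cyclin that drives entry into mitosis, fell from 8.70 ± 0.39 in DMSO (SD, n = 2) to 4.57 ± 0.03 in CPT late (SD, n = 2), 17.5-fold. The kinetochore gene CENPF fell 13.3-fold, the spindle checkpoint kinase gene BUB1B 9.98-fold and the kinesin gene KIF23 9.47-fold. Relative to the DMSO mean the list median was −1.80 at 15 h and −2.01 at 20 h, whereas it lay between −0.06 and 0.03 on the CPT early arrays. The camera adjusted p was 3.34e-17, and adjusted p = 0.21 with an estimated correlation.

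**Figure D1:**
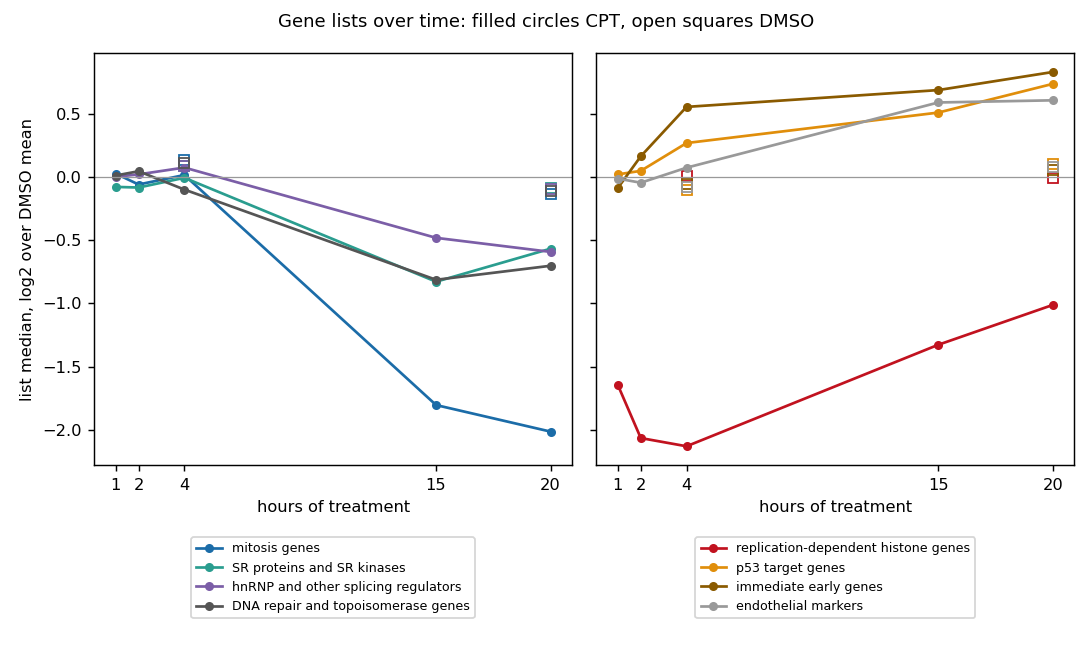
Median of 8 gene lists on each array, as the log2 difference from the mean of the DMSO arrays (y axis), against hours of treatment (x axis). Filled circles joined by lines are CPT arrays and open squares are DMSO arrays, with 1 array per time; the mitosis list reads −1.80 at 15 h and −2.01 at 20 h, and the histone list −1.65 at 1 h.

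Lists of RNA splicing genes moved unevenly in CPT late. Among SR proteins and SR kinases, which set splice site choice, 12 of 23 were lower and 1 higher (median −0.69, camera adjusted p = 3.12e-06, adjusted p = 0.21 with an estimated correlation). SRSF3 fell from 9.82 ± 0.11 to 8.07 ± 0.38 (SD, n = 2 each), and SCAF11 fell by 2.33, the kinase gene SRPK2 by 1.74 and SRSF10 by 1.47 on the log2 scale. Among hnRNP and other splicing regulators 19 of 36 were lower and 1 higher (median −0.54, camera adjusted p = 5.66e-08, adjusted p = 0.242 with an estimated correlation), led by RBM25 (−2.47), MBNL1 (−2.26), MBNL2 (−2.23) and RBM39 (−1.94). Core spliceosome and exon junction complex genes were less uniform, with 16 of 61 lower and 8 higher (median −0.10, camera adjusted p = 0.00885, adjusted p = 0.474 with an estimated correlation). LSM6 fell by 2.38, SNRPD1 by 2.16, CDC40 by 2.08 and SNRPA1 by 1.84, while RBM8A of the exon junction complex read 0.27 and did not pass. Without the 4 h DMSO array the spliceosome list had 4 genes higher, a median of 0.06 and a camera adjusted p = 0.082, and without the 20 h CPT array 5 genes were higher. The 1 higher gene among SR proteins did not pass without either of those arrays, nor the 1 higher hnRNP gene without the 20 h DMSO array. After centring each array on its gene median 13 SR genes were lower and 1 higher, 20 hnRNP genes lower and 0 higher, and 21 spliceosome genes lower and 5 higher, with a spliceosome median of −0.34.

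Genes of DNA repair and topoisomerases also moved downward, with 22 of 36 lower and 3 higher (median −0.66, camera adjusted p = 2.45e-08, adjusted p = 0.21 with an estimated correlation). Without the 15 h array, the 20 h CPT array or the 4 h DMSO array the 3 higher genes became 1, 0 and 1. RAD50, of the complex that binds double-strand breaks, fell by 2.27, the mismatch repair gene MSH6 by 1.88, TOP2B by 1.86 and BRCA1 by 1.79. TOP1 fell by 0.64 (adjusted p = 0.0296) and TDP1, whose enzyme removes trapped topoisomerase I from DNA, by 0.66 (adjusted p = 0.0393). Both calls were near the threshold and were lost when single arrays were left out, with fewer arrays left to estimate the spread. Among the other settings tried, arrays left out included, TOP1 passed in 12 of 18 and TDP1 in 8 of 17. TOP1 read −0.37 (adjusted p = 0.183) without the 20 h CPT array, −0.58 (0.134) without the 4 h DMSO array and −0.70 (0.0598) without the 20 h DMSO array. TDP1 read −0.34 (0.296) without the 15 h array, and did not pass without the 2 h array (0.0502), the 4 h DMSO array (0.115) or the 20 h DMSO array (0.108). Of 39 DNA replication genes 13 were lower and 5 higher (median −0.23, camera adjusted p = 0.00506, adjusted p = 0.474 with an estimated correlation), including RFC1 (−2.14), MCM10 (−1.90), GINS1 (−1.87) and PCNA (−1.41). The 5 higher replication genes became 3 without the 15 h array, 1 without the 20 h CPT array, 1 without the 4 h DMSO array and 2 without the 20 h DMSO array. Heat shock and chaperone genes had 6 lower and 1 higher of 19, a median of −0.00 and a mean of −0.41 (camera adjusted p = 0.0155, adjusted p = 0.444 with an estimated correlation). Without the 4 h DMSO array its adjusted p was 0.051, and 0 members were higher without that array or without the 15 h array. HSPA8, an abundant chaperone gene, fell from 10.19 ± 0.16 to 7.90 ± 0.03 (SD, n = 2 each), and DNAJA1 (−2.01), HSPA9 (−1.33) and HSPA4 (−1.26) fell too. After centring 24 repair genes were lower and 0 higher, 14 replication genes lower and 1 higher (median −0.47) and 7 chaperone genes lower and 0 higher (median −0.24).

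Higher in CPT late were p53 target genes, with 14 of 28 higher and 1 lower (median 0.58, camera adjusted p = 0.0221, adjusted p = 0.474 with an estimated correlation). GADD45A, a growth arrest gene, rose from 5.04 ± 0.33 to 8.21 ± 0.30, 8.98-fold, and CDKN1A from 5.47 ± 0.28 to 7.20 ± 0.17, 3.33-fold (SD, n = 2 each). TP53INP1 (2.52), TRIAP1 (2.51) and SESN1 (2.02) rose too. MDM2, which encodes the ubiquitin ligase that degrades p53, was the 1 lower member: it fell from 7.49 ± 0.14 to 6.49 ± 0.03 (adjusted p = 0.00414). This value is a median over probe sets that diverged: of 128, 17 were higher and 36 lower relative to it. Lower p53 targets numbered 2 without the 4 h or the 20 h CPT array. Immediate early genes had 11 of 22 higher and 0 lower (median 0.74, camera adjusted p = 0.0335, adjusted p = 0.514 with an estimated correlation), led by the stress transcription factor gene ATF3 (2.96), EGR2 (2.52), CCN2 (2.08) and IER2 (1.97), while FOS (0.69) and MYC (−1.15) did not pass. FOS passed without the 20 h DMSO array (1.07, adjusted p = 0.047), and MYC passed as lower without the 1 h array (0.0207) or the 2 h array (0.0174). Without the 20 h CPT array the camera adjusted p was 0.0549 for the p53 list and 0.0625 for the immediate early list, and without the 20 h DMSO array it was 0.0878 for the latter. With each array centred on its gene median 12 p53 targets were higher and 1 lower, and 8 immediate early genes were higher.

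Markers of cell types that this line should lack read higher on the same arrays. The p53 and immediate early lists, with camera adjusted p = 0.0221 and 0.0335, are not set clearly apart from such unrelated lists by that test. Of 10 endothelial markers 9 were higher (median 0.61, camera adjusted p = 0.0299, adjusted p = 0.444 with an estimated correlation), and of 10 leukocyte markers 5 were higher, 6 when adjusted over the list alone (median 0.64, camera adjusted p = 0.0296, adjusted p = 0.444 with an estimated correlation). Without the 20 h DMSO array these lists had adjusted p = 0.0518 and 0.0615. The 9 endothelial markers became 2 without the 15 h array, 3 without the 20 h CPT array and 2 without the 4 h DMSO array. Fibroblast markers had 4 of 10 higher with a median of 0.51 (camera adjusted p = 0.125), and epithelial markers, the line's own type, had 3 higher, 2 when adjusted over the list alone, and 1 lower of 11 with a median of −0.01 (adjusted p = 0.553). Fibroblast markers numbered 1 without the 15 h array and 2 without the 4 h DMSO array, and higher epithelial markers 1 without either of these and 0 without the 20 h CPT array. NF-kappaB target genes had 14 of 20 higher and 2 lower with a median of 0.66, yet the list did not pass (camera adjusted p = 0.0878; 0.0393 without the 20 h CPT array). IL6 rose by 1.22 and CXCL1 by 0.88, while NFKB1 (−1.19) and REL (−0.99), which encode subunits of the factor, fell. Without the 15 h array or without the 4 h DMSO array 3 members of that list were higher, and without the 20 h CPT array 9. CXCL1 did not pass without any of these arrays (adjusted p from 0.0943 to 0.22) and read −0.09 from B, F and T probe sets alone, and REL did not pass without the 20 h CPT array (0.0501) or the 4 h DMSO array (0.0573). All of these medians stand beside an all-gene median of 0.34, and with each array centred on its gene median 2 endothelial markers, 4 leukocyte markers, 2 fibroblast markers and 3 NF-kappaB genes were higher, and of epithelial markers 0 were higher and 1 lower (median −0.25).

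Other lists went both ways in CPT late. Replication-dependent histone genes had 5 lower, 6 when adjusted over the list alone, and 2 higher of 10 (median −1.17, camera adjusted p = 0.00998, adjusted p = 0.21 with an estimated correlation). H4C8 fell by 4.24, H2BC4 by 2.88 and H2AC6 by 2.45, and H2BC5 rose from 5.29 ± 0.01 to 7.96 ± 0.49 (SD, n = 2 each). Without the 15 h array or the 20 h DMSO array 1 histone gene was higher. Without the filter on dim probe sets the list median was 0.20, with H4C8 at 1.41 and H2AC6 at 0.68. After centring 1 histone gene was higher and 6 lower. Apoptosis genes had 6 higher and 5 lower of 25 (median 0.14, mean 0.00, camera direction down with adjusted p = 0.586), among them TNFRSF1A (−2.15), the survival gene BCL2L1 (−1.27), CASP8 (−1.19), BIRC2 (−1.12) and CASP2 (−0.70). After centring the balance turned, with 3 higher and 6 lower (median −0.09). The 6 higher became 2 without the 15 h array and 1 without the 4 h DMSO array, and the 5 lower became 2, 3 and 2 without the 15 h array, the 20 h CPT array and the 4 h DMSO array. CASP2 and BIRC2 did not pass without any of these 3 arrays (adjusted p from 0.0581 to 0.125), and BCL2L1 did not without the 15 h array (0.0565) or the 4 h DMSO array (0.109). Ribosomal protein genes had 18 higher, 17 when adjusted over the list alone, and 2 lower of 48 (median 0.19, camera adjusted p = 0.305), with RPS15 at 1.37, RPS2 at 0.83, RPS9 at 0.79 and RPL19 at 0.77. Without the 4 h DMSO array 10 were higher and 1 lower, and RPL19 did not pass (0.0833). Their median was −0.04 after centring, with 9 higher and 5 lower. Unfolded protein and amino acid stress genes had 3 higher and 2 lower of 16 (median 0.36, camera adjusted p = 0.702): CHAC1 (1.56) and DDIT4 (0.95) rose, and SLC7A11 (−1.28) and PSAT1 (−0.91) fell. PSAT1 did not pass without the 15 h array (0.0757) or the 4 h DMSO array (0.0545), which leaves 1 lower.

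Over all 16148 genes, limma called 5399 higher and 2908 lower in CPT late than in DMSO, 954 and 1889 of them by more than 2-fold. The 10 largest increases were EID2B (4.19), H2AJ (3.87), THAP2 (3.28), C6orf52 (3.21), the RNA kinase gene CLP1 (3.19), GADD45A (3.17), SGK1 (3.15), ANKRA2 (3.15), DORIP1 (3.04) and ATF3 (2.96). The 10 largest decreases were MALSU1 (−4.26), H4C8 (−4.24), CCNB1 (−4.13), ARHGAP29 (−4.05), KITLG (−3.97), the chromatin remodeller gene CHD1 (−3.88), TLK1 (−3.83), ROCK2 (−3.82), CENPF (−3.73) and NDC80 (−3.69). In this ranking EID2B rests on few kept probe sets, and H4C8 reversed without the filter on dim probe sets. The late arrays did not overlap the DMSO arrays in 78.6% of genes, against 33.3% by chance. The median gene read 0.34 higher, and with each array centred on its gene median 2081 genes were higher and 3420 lower. Quantile re-normalization left the split much as it was, with 5725 higher and 2846 lower. With no filter on dim rows the median gene read 0.15 higher, with 3877 genes higher and 2439 lower. Among 947263 kept named probe sets the split was the other way, 68515 higher and 134465 lower. The split of genes depends on level too: among the 5383 genes in the upper tercile of level 1091 were higher and 1903 lower, with a median of −0.14. The count of 8307 became 5315 without the 15 h array, 4957 without the 20 h array and 4074 without the 4 h DMSO array. In a fit with time as a block over the 4 and 20 h arrays alone, and in a fit of all 5 CPT arrays against DMSO, 2 genes passed. The first joins the 4 and 20 h differences and the second mixes the windows, so neither tests CPT late alone.

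The direct comparison of CPT late with CPT early asked how the response changes with time, and it uses the DMSO arrays only for the spread. CCNB1 fell from 8.62 ± 0.16 (SD, n = 3) to 4.57 ± 0.03 (SD, n = 2), and 25 of 29 mitosis genes were lower (median −1.86, camera adjusted p = 1.29e-18, adjusted p = 0.263 with an estimated correlation), CENPF (−3.39), BUB1B (−3.23) and KIF11 (−3.17) among them. Lower too were 20 of 36 hnRNP and other regulators (adjusted p = 1.98e-08), 22 of 36 DNA repair genes (8.57e-09), 18 of 39 DNA replication genes (1.42e-05), 10 of 23 SR proteins and SR kinases (1.2e-05) and 24 of 61 core spliceosome genes (3.5e-05). With an estimated correlation these lists had an adjusted p between 0.263 and 0.332. Higher were 5 replication, 5 spliceosome, 2 SR, 2 repair and 0 hnRNP genes. Without the 20 h CPT array 15 spliceosome genes were lower and 2 higher, 0 replication and 0 repair genes were higher, and 1 SR gene was. Higher replication genes numbered 2 without the 1 h or the 2 h array, and higher repair genes 1 without the 1 h, the 2 h or the 15 h array. After centring 29 spliceosome genes were lower and 1 higher, 15 SR genes lower and 1 higher, and 24 hnRNP, 27 repair and 21 replication genes lower with 0 higher. MBNL1 (−2.53), LSM6 (−2.54), SNRPA1 (−2.20), RBM25 (−2.20), RAD50 (−2.10), GINS1 (−2.07), RFC1 (−2.07), SCAF11 (−1.98) and NBN (−1.82) show their range. CLK1, a kinase of SR proteins, moved the other way, from 4.36 ± 0.36 (SD, n = 3) to 5.90 ± 0.23 (SD, n = 2), adjusted p = 0.00131. TOP1 fell by 0.62 (adjusted p = 0.0228), but did not pass without the 2 h array (0.0508), the 4 h CPT array (0.053) or the 20 h CPT array (0.184). MDM2 fell by 1.39 and CASP2 by 0.86, and TDP1 (−0.47), MYC (0.04), RBM8A (0.07) and FOS (0.50) did not pass. TDP1 passed without the 20 h CPT array (−0.78, 0.0364) and FOS without the 4 h CPT array (0.79, 0.0346).

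Histone genes differed between the windows too. Of 10 replication-dependent histone genes 8 were higher in CPT late than in CPT early and 1 was lower (median 0.91), but the list did not pass against other genes (camera adjusted p = 0.0798), and after centring 4 were higher and 1 lower. H2BC5 rose by 3.24 to a level above that in DMSO, H2BC12 by 1.48 and H2AC11 by 1.02. H4C8 fell by 1.82, a difference that reversed without the filter on dim probe sets. Without the 15 h or the 20 h CPT array 5 were higher, and without the 1 h array the list passed (adjusted p = 0.0422). H2AC11 did not pass without the 15 h array (0.084), nor H2BC12 without the 2 h array (0.051) or the 20 h CPT array (0.138). Of 28 p53 target genes 15 were higher and 1 lower, or 2 lower without the 2 h or the 20 h CPT array (camera adjusted p = 0.0373, adjusted p = 0.521 with an estimated correlation, and 0.0754 with camera without the 20 h CPT array). GADD45A rose by 2.91, TP53INP1 by 2.75, TRIAP1 by 1.89 and CDKN1A by 1.73. Immediate early genes had 12 of 22 higher (adjusted p = 0.0518), with ATF3 at 2.40, EGR2 at 1.62, IER3 at 1.48 and IER2 at 1.28. After centring 12 p53 targets were higher and 2 lower, and 5 immediate early genes were higher and 1 lower. The immediate early list passed without the 4 h CPT array (0.00354) or the 15 h array (0.0263). Without the 20 h CPT array 4 of its genes were higher, and EGR2 (0.0634), IER3 (0.117) and IER2 (0.0586) did not pass. Endothelial markers (9 of 10 higher, adjusted p = 0.0359) and leukocyte markers (8 of 10 higher, adjusted p = 0.0373) rose on the same arrays, with adjusted p = 0.332 and adjusted p = 0.407 with an estimated correlation, but after centring 2 of each were higher. Endothelial markers numbered 2 without the 15 h array and 3 without the 20 h CPT array. Leukocyte markers numbered 4 without the 2 h array, 3 without the 15 h array and 2 without the 20 h CPT array, where their list had adjusted p = 0.0512. Of NF-kappaB target genes 11 of 20 were higher (camera adjusted p = 0.122), TNF (0.89), IL6 (0.81) and TNFAIP2 (0.77) among them, and NFKB1 fell by 1.25. After centring 3 were higher and 2 lower. Among the other settings tried TNF passed in 14 of 16, IL6 in 13 of 17, TNFAIP2 in 13 of 16 and NFKB1 in 16 of 16. Without the 2 h, the 15 h and the 20 h CPT array 5, 2 and 7 NF-kappaB genes were higher, and IL6 (0.084) and TNFAIP2 (0.0603) did not pass without the 15 h array. The remaining lists did not pass, except heat shock genes without the 1 h array (0.0447). Values there include HSPA8 (−2.21), DNAJA1 (−1.86), HSPA4 (−1.47) and HSPA9 (−1.34) among chaperones, BCL2L1 (−1.69), TNFRSF1A (−1.43), BIRC2 (−0.99) and CASP8 (−0.95) among apoptosis genes, SLC7A11 (−1.42), PSAT1 (−1.31), DDIT4 (1.08) and CHAC1 (1.01) among stress genes, and RPS15 (0.99), RPL34 (−0.76), RPL12 (0.66) and RPS2 (0.64) among ribosomal protein genes. BIRC2 did not pass without either late array (0.0695 and 0.0712), nor RPL12 without the 15 h array (0.0527).

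In all, 5846 genes were higher and 3064 lower in CPT late than in CPT early with limma, and 2152 and 3631 after centring. The late and early arrays did not overlap in 74.5% of genes, against 20% by chance. Beyond H2BC5, GADD45A and TP53INP1 the largest increases were DORIP1 (2.96), LRATD2 (2.85), C6orf52 (2.75), ZNF425 (2.72), CLP1 (2.65), FICD (5.67-fold) and ARRDC3 (2.42). The largest decreases were CCNB1 (−4.05), MALSU1 (−3.99), ARHGAP29 (−3.91), ROCK2 (−3.81), KITLG (−3.75), TENT4B (−3.51), the receptor tyrosine kinase gene MET (−3.47), PDCD10 (−3.45), TLK1 (−3.45) and NDC80 (−3.40). The count of 8910 became 5226 without the 15 h array and 4896 without the 20 h array.

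The array design asks whether exons and junctions change apart from the level of their gene. Each kept probe set was therefore expressed relative to the median of its gene, in 944048 probe sets of 15600 genes. In CPT early 11 probe sets were higher and 5 lower, in 14 genes. The largest changes there were in WAC, where a Y probe set fell by 6.03 and a D probe set by 4.98 on the log2 scale, and in UGGT1 (−5.17) and R3HDM1 (−4.64). Increases were found in PNLDC1 (4.52), TAP1 (4.35), YIPF4 (4.28), CACNA1A (3.97), CARF (3.92) and RAD51B (3.91). In 5 of these 10 the lower group lay under the cut on dim rows, 2.95, on each of its arrays, which leaves their size uncertain. This count was between 0 and 10 when any of the 7 arrays was left out, 0 without the 4 h CPT array, either late array or either DMSO array, 1 without the 2 h array and 10 without the 1 h array.

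In CPT late 31029 probe sets were higher and 20545 lower relative to their gene, 5.46% of those tested, in 8949 genes. The 10 largest changes were all increases and lay in PSMD12 (7.35), HYPK (7.24), CHAF1A (7.23), EIF2S2 (7.04), HELZ (6.74), ANKHD1 (6.70), NOP56 (6.68), TPR (6.65), CCDC77 (6.63) and NCAPG (6.63). The PSMD12 probe set rose from 2.03 and 1.74 on the DMSO arrays to 7.27 at 15 h and 8.53 at 20 h. In 7 of these 10 both DMSO values lay under the cut on dim rows, 2.95, near the floor of the measurement, so the size and the order of these changes are uncertain. By the share of probe sets that passed, the leading genes were LSM8, a member of the spliceosome list (19 of 26), MALSU1 (14 of 21), LY6G5C (15 of 25), CCDC122 (3 of 5) and GLCE (13 of 23). In MDM2 17 probe sets were higher and 36 lower of 128. CASP2 had 3 of 77, TDP1 10 of 115, CDKN1A 4 of 79, RBM8A, FOS and MYC 1 each, and TOP1 0 of 122. The count of 51574 became 32159 without the 15 h array, 11483 without the 20 h array, 7082 without the 4 h DMSO array and 26984 without the 20 h DMSO array. With time as a block over the 4 and 20 h arrays, and with all 5 CPT arrays as 1 group, it was 0. Both fits join early with late CPT arrays, so neither tests CPT late alone.

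Probe set names end in a letter whose meaning is not given in the sources used here, and the letters behaved differently in CPT late. Of 33108 Y probe sets 3394 were higher and 192 lower relative to their gene (median 0.55), and of 41239 Z probe sets 3359 were higher and 186 lower (median 0.42). Of 77443 E probe sets 4341 were higher and 1323 lower (median 0.16). X probe sets (1733 higher, 2879 lower) and T probe sets (1936 higher, 3878 lower) went the other way, with medians of −0.06 and −0.09. Y probe sets stood at 0.01, 0.07 and 0.20 relative to the DMSO mean at 1, 2 and 4 h and at 0.52 and 0.62 at 15 and 20 h, and Z probe sets at −0.02, −0.01 and 0.03 and then at 0.43 and 0.45. The DMSO arrays differed as well, which may be technical or due to time: from the 4 h to the 20 h array the median change was 0.03 for Y, 0.22 for Z and 0.09 for E. The medians in CPT late depend on the rows kept. With no filter on dim rows they were 0.20 for Y, 0.22 for Z and 0.13 for E, and with rows kept by the CPT early arrays alone 0.54, 0.42 and 0.15, both settings chosen after seeing the data. Before the gene level is taken out the array medians over all rows were higher by 0.12 for Y, 0.15 for Z and 0.12 for E on the late arrays than on the DMSO arrays, on average, while the DMSO arrays differed by −0.05, −0.02 and −0.03 between 20 and 4 h. The letters were not refitted with arrays left out.

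**Figure D2:**
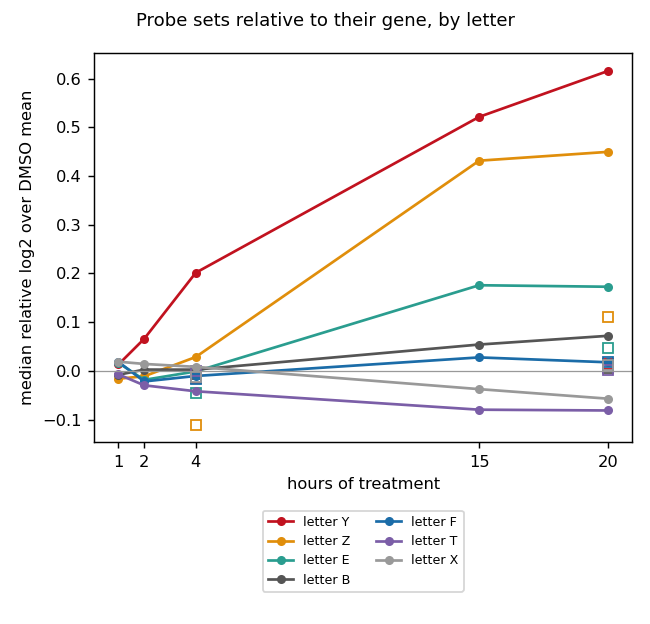
Median change of probe sets relative to their gene, as the log2 difference from the mean of the DMSO arrays (y axis), for 7 probe set letters against hours of treatment (x axis). Filled circles joined by lines are CPT arrays and open squares are DMSO arrays, 1 array per time; letter Y reads 0.20 at 4 h and 0.62 at 20 h.

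In CPT late against CPT early 32251 probe sets were higher and 22810 lower relative to their gene, in 8528 genes. The largest were in PPFIA1 (6.66), CHAF1A (6.22), EIF2S2, CNOT1 (6.03), WDR43 (5.94), MED13 (5.91), RPAP2 (5.84) and SMCHD1 (5.71), and in ABCF2, whose E and X probe sets rose. In 4 of these 10 each CPT early value lay under the cut on dim rows. By share, KBTBD3 (5 of 6), MALSU1 (14 of 21), ABHD17C (22 of 34), GNAI1 (35 of 59) and JPH1 (20 of 34) led. MDM2 had 40 of 128 and TOP1 2 of 122. The count of 55061 became 23775 without the 1 h array, 24448 without the 2 h array, 32485 without the 15 h array and 10678 without the 20 h array.

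The series title asks whether genes of splicing factors are affected preferentially. Among the 120 measured genes of the 3 splicing lists, 94 (78.3%) had at least 1 probe set that changed relative to the gene in CPT late, against 8855 of 15480 other genes (57.2%), an odds ratio of 2.70 with a 95% interval of 1.73 to 4.36 (Fisher's exact test, two-sided, p = 1.67e-06). Splicing genes also carry more tested probe sets, a median of 87.5 against 45. In a logistic regression (n = 15600 genes) with the number of probe sets and the mean level as covariates the odds ratio was 1.23 (0.764 to 1.99, p = 0.392). Counted by probe set, 6.04% passed in splicing genes and 5.46% in other genes. The splicing genes with the largest shares after LSM8 were LSM6 (9 of 28), SNRNP40 (15 of 49), RBM25 (49 of 164) and SRPK2 (38 of 129). No splicing gene had a passing probe set in CPT early. The odds ratio from Fisher's exact test was 1.51 (p = 0.0487) without the 20 h CPT array.

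Only 4 and 20 h had a solvent control of their own. The difference CPT minus DMSO at 4 h correlated with that at 20 h at r = 0.40 across 16148 genes, which are not independent replicates. No control array is shared between these differences, and with 1 array on each side neither has a test. The 20 h difference spread more widely, with an SD of 0.84 over genes against 0.43 at 4 h, while the 20 h DMSO array differed from the 4 h DMSO array with an SD of 0.39. By more than 2-fold, 224 genes were higher and 281 lower at 4 h, 1055 higher and 1858 lower at 20 h, and 176 higher and 97 lower between the DMSO arrays. Histone genes had medians of −2.10 at 4 h and −1.05 at 20 h, mitosis genes −0.11 and −1.83, SR proteins and SR kinases −0.10 and −0.67, and p53 target genes 0.40 and 0.69. Immediate early genes had medians of 0.68 and 0.76. Between the DMSO arrays these lists moved by −0.02, −0.27, −0.18, 0.21 and 0.11 in the same order.

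CPT slows RNA polymerase on DNA, so the change was set against gene length, taken from the GRCh38.p14 annotation, for 15990 genes. The longer the gene, the lower its change in CPT late, with Spearman rho = −0.39 across genes. Over all genes the median change was 0.57, 0.41, 0.13 and 0.01 from the shortest to the longest quartile. These stand beside an all-gene median of 0.34, which was 0.10 after centring and 0.15 with no filter on dim rows. Of the longest quartile 1330 of 3998 genes were lower and 772 higher. In the lower tercile of level the longest quartile stood at 0.32, with 521 of 1785 genes higher and 203 lower, and in the middle tercile at −0.13, with 226 of 1248 higher and 449 lower. In the upper tercile of level rho was −0.58. There the shortest quartile, up to 11.3 kb, had a median change of 0.50, with 639 of 1479 genes higher and 99 lower. The longest quartile, from 73 kb up, had a median of −1.14, with 25 of 965 genes higher and 678 lower. The quartiles between had medians of 0.01 and −0.61. In CPT early rho was −0.23, and −0.13 without the 4 h DMSO array. The difference between the DMSO arrays had rho = −0.09 over all genes and −0.23 in that tercile.

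**Figure D3:**
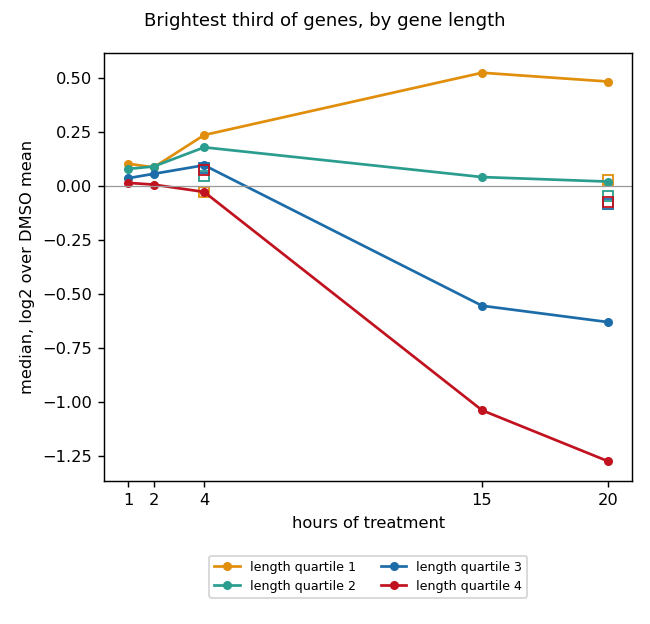
Median change of the genes in the upper tercile of level, as the log2 difference from the mean of the DMSO arrays (y axis), for 4 quartiles of gene length (1 is the shortest) against hours of treatment (x axis). Filled circles joined by lines are CPT arrays and open squares are DMSO arrays, 1 array per time; the longest quartile reads −1.04 at 15 h and −1.28 at 20 h.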

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

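Tests of gene length against level and against time in culture, of compression and of time in culture letter by letter, and of level and length for core spliceosome, DNA replication, heat shock and histone genes, were chosen only after the results were seen. The limit that sets a list apart from drawn lists was given its sampling interval after the value for DNA repair genes had been seen, which leaves that list open where the bare limit would have set it apart.

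Gene lists differed between the early and the late response to CPT in a direct test of CPT late against CPT early, which is what brought them here. Mitosis genes had a median difference of −1.86, hnRNP and other splicing regulators −0.64, DNA repair and topoisomerase genes −0.62, DNA replication genes −0.48, SR proteins and SR kinases −0.47 and core spliceosome genes −0.33. p53 target genes had a median difference of 0.65, leukocyte markers 0.62 and endothelial markers 0.55. None of these passed with an estimated correlation.

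Single genes that passed in CPT early and differed again between the windows were EID2B (2.07 higher in CPT late than in CPT early), H2BC11 (1.18), H1-2 (0.96), H2BC21 (0.92), H2AC6 (0.84) and H4C8 (−1.82). All but H4C8 among these histone genes lay nearer to the DMSO level in CPT late, but they were chosen as lower on the same CPT early arrays, so some return is expected from the choice alone, and how much was not measured. Without the filter on dim probe sets the H4C8 difference was 1.61, and EID2B rests on few kept probe sets.

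Probe sets unnamed here hold a signal outside the comparisons of genes. In CPT late against DMSO, 20953 of 107207 kept unnamed probe sets passed, 8012 higher and 12941 lower, which is 19.5% against 21.4% of named probe sets. In CPT early 42 were higher and 54 lower.

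The change in CPT late was lower the longer the gene, and the size of it depended on level: the longest quartile had a median of 0.32, −0.13 and −1.14 from the lower to the upper tercile, and 0.01 over all genes. If a floor of the measurement in dim genes made the pattern it would vanish among bright ones, but in the upper tercile of level rho was −0.58 (95% interval over genes −0.60 to −0.56). The number of probe sets per gene does not account for it either, since rho was −0.23 even in the quartile of probe set number where it came nearest 0. Time in culture as the whole cause is argued against by the 20 h CPT array against the 20 h DMSO array, with rho = −0.56 in the upper tercile, though this rests on 1 array on each side and the DMSO arrays alone gave −0.23. Slowed transcription through long genes may be a candidate explanation, but no test of it was made; RNA read from the start to the end of long genes at each time would test it.

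Y and Z probe sets rose relative to their gene in CPT late, and E probe sets less. Keeping rows by a mean that includes the late arrays favours rows that rose, but with rows kept by the CPT early arrays alone the median was still 0.474 for Y and Z and 0.151 for E. Dim probe sets rising in general would leave no excess at matched level, but the excess over other letters was 0.51 for Y and Z and 0.20 for E. Compression, where weak probe sets lag as their gene falls, would leave no excess at matched level in genes that went up. There the excess over other letters was 0.354 for Y and 0.162 for Z, and for E 0.0203 (interval 0.00881 to 0.0298), too small to decide, so for E compression stays open. This comparison replaced, after its values were seen, one set beforehand without the other letters and with Y and Z together (0.163). The median of the other letters in those genes was −0.0847 beside 0.267 for Y, 0.085 for Z and −0.0522 for E. In genes not called higher the medians were larger, 0.838 for Y, 0.738 for Z and 0.333 for E. Compression may therefore still add to the rise, and for Y and Z it is argued against only as the whole cause. That argument is limited, because genes were called higher from medians that include their Y, Z and E rows. The choice favours genes where these rows rose, and how much of the excess it made was not measured. Time in culture as the whole cause is argued against for Y and Z, whose lower late array still read 0.494 and 0.325 over the 20 h DMSO array. Their 4 h CPT array read 0.214 and 0.138 over the 4 h DMSO array. Each value rests on 1 control array, and Z moved by 0.22 between the DMSO arrays. Relative to the DMSO mean, Z stood at −0.11 on the 4 h DMSO array, 0.03 on the 4 h CPT array and 0.11 on the 20 h DMSO array. For Z the 4 h pair thus decides nothing, and the argument rests on the late arrays. For E the lower late array and the 4 h CPT array read 0.13 and 0.0354 over their controls, with 0.0925 between the DMSO arrays. There time cannot be told apart from the drug. That the 4 h pair must agree was asked for after these values were seen. If Y and Z read unspliced RNA, which is a guess as the letters are not explained in the sources used here, retained introns could underlie their rise; no test of that was made.

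Long, bright genes fell most, so each list that passed in CPT late against DMSO was set against 10000 lists drawn with the same level and length. The differences between CPT late and CPT early were not set against drawn lists. The mitosis and histone medians lay at percentile 0 and that of SR proteins and SR kinases at 0.31, so unrelated genes of the same level and length rarely fell as far. Drawn genes are independent, while the estimated correlation was 0.4 among mitosis genes, 0.0995 among SR genes and −0.0413 among histone genes. The drawn range may therefore be too narrow. The SR median, −0.692, lay near its lower drawn limit of −0.473, which leaves level and length open there. The mitosis median, −1.91, lay far below its limit of −0.599. The draws used values with the filter on dim probe sets, and without that filter the histone list did not fall. DNA repair genes (2.42) and hnRNP genes (7.41), and on the higher side p53 targets (97.2), immediate early genes (96.8) and endothelial markers (96.4), lay between the limits, and level and length as the cause cannot be told apart from a shift of their own. Leukocyte markers (85.3), core spliceosome genes (52.3), DNA replication genes (36.3) and heat shock genes (30) lay where level and length alone would put them. No biological explanation for the lists was tested.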

How the results depend on the processing

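Chosen only after the results were seen were centring on the gene median, B, F and T probe sets alone, the upper tercile of level alone for counts of genes, the estimated correlation, CPT late against CPT early for splicing genes (odds ratio 3.18, or 1.39 with probe set number and level as covariates, p = 0.179), and other choices of rows for the letters. Except where a construction is named, the cause was not tested.

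H4C8 reversed without the filter on dim probe sets, to 1.41 in CPT late against DMSO and 1.61 against CPT early. Under that setting H2AC6 read 0.68 in CPT late, the histone list 0.20 and EID2B in CPT early −0.39. CXCL1 in CPT late read −0.089 from B, F and T probe sets. In CPT early, with 1 array left out, the mitosis median ran from −0.112 to 0.148 and the hnRNP median from −0.0665 to 0.103, with both lists up without the 4 h DMSO array. Over named genes 2965 of 3331 settings kept direction and side of the threshold, 321 lost the call, 11 gained it, 29 uncalled values changed sign and 5 reversed. For lists these were 705 of 810, 51, 25, 26 and 3.

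Genes changed in CPT early, 15, numbered 29 with the mean of kept rows, 9 from B, F and T probe sets, 9 after centring, 8 with the stricter filter and 1 with no filter. They numbered 2 with all 5 CPT arrays as 1 group and 2 with time as a block, which keeps 4 arrays, and 6 to 32 with 1 array left out. In CPT late 8307 became 5501 after centring, 2994 in the upper tercile (fewer genes tested, and mostly lower, 1903 against 1091), 2 with all 5 CPT arrays as 1 group, which mixes the windows, 2 with time as a block, and 4074 to 8085 with 1 array left out. For CPT late against CPT early 8910 became 5783 after centring, 3067 in the upper tercile and 4896 to 9220 with 1 array left out. With an estimated correlation 1 list passed in CPT early, 0 in CPT late and 0 between the windows, against 4, 12 and 9.

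Relative probe set changes in CPT early, 16, numbered 40 relative to the gene mean, 1 without the intensity trend, 0 with no filter, 0 with the stricter filter and 0 to 10 with 1 array left out. In CPT late 51574 became 89928 with no filter, 0 with all 5 CPT arrays as 1 group, 0 with time as a block and 7082 to 44803 with 1 array left out. Between the windows 55061 became 105292 with no filter and 10678 to 50094 with 1 array left out. The odds ratio of splicing genes, 2.70, was 1.23 in the logistic regression and 0 in CPT early, where no splicing gene had a call, and 1.51 to 2.88 with 1 array left out.

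The median relative change in CPT late with no filter was 0.201 for Y, 0.219 for Z, 0.127 for E and −0.0781 for T probe sets, against 0.551, 0.419, 0.158 and −0.0867; with rows kept by the CPT early arrays alone E stood at 0.151 and T at −0.0824.

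The rho of gene length in CPT late, −0.39, was −0.30, −0.47 and −0.58 from the lower to the upper tercile of level, −0.45 with no filter and −0.39 to −0.37 with 1 array left out; in CPT early it was −0.25 to −0.13. The time-matched r of 0.40 was 0.48 with the mean of kept rows and 0.35 with no filter. The 7 arrays, with no time point repeated, limit every count.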

Other observations

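The DMSO arrays differ from each other. Between 4 and 20 h in solvent NF-kappaB target genes read higher by a median of 0.35, while medians were −0.23 for core spliceosome genes and −0.22 for chaperone genes. With 1 array at each time these have no test. Against the 20 h DMSO array the 20 h CPT array had NF-kappaB genes at 0.38 and epithelial markers at −0.14.

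Epithelial markers lay at percentile 0.97 of lists drawn with the same level and length in CPT late, since their drawn lists had a median of 0.45 and the markers −0.01. Histone genes lay at percentile 0, with −1.17 against 0.55, but their median was not lower without the filter on dim probe sets.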
